A study of Mus musculus with 6 samples.

How the data were processed

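Gene expression was measured by RNA-seq of polyadenylated RNA in 3 samples and accessible chromatin by ATAC-seq in 3 samples of R1 mouse embryonic stem cells treated with retinoic acid to day 6. RNA-seq libraries were made with a commercial kit for Illumina sequencing and ATAC-seq libraries with Tn5 transposase and PCR, per the labels' protocols. Samples were assigned to the RNA-seq or the ATAC-seq group from their titles, which also number the replicates. The design holds this condition alone, so no test between conditions was made. Bowtie, Cufflinks and the genome build mm9 are named in the submitters' processing notes; their versions and settings are not given in the sources used here.

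The deposited RNA-seq table holds a column for each replicate and 24002 gene symbols. Its header names no unit, and its values were read as FPKM (fragments per length of transcript and mapped fragments) because the submitters' processing notes name Cufflinks and the values have the form of its estimates. Whether the authors scaled the libraries to each other before they deposited FPKM is not given in the sources used here. FPKM divides by gene length, so a handful of fragments on a very short gene gives a large value, and an exact 0 or a very small value can be a failed estimate: Ndufs5, a gene of the respiratory chain chosen after its values were seen, was listed at 0.000128, 0.000183 and 0.000142 FPKM. Genes listed at 0 are therefore only said to be listed at 0. Strand use in counting is not given, so overlapping and antisense genes are uncertain. The deposited ATAC-seq regions form a joint set named by the descriptions of all 3 ATAC-seq samples, with a chromosome, a start, an end and a score per region. The scale of the deposited score, the region caller, its threshold, the handling of the Tn5 offset and any pooling of samples are not given in the sources used here, and the score was used only to describe and rank regions within the set. Coordinates are in mm9 and are given 1-based.

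The relative depth of the RNA-seq libraries was estimated from genes between 0.001 and 0.1 FPKM in both libraries of a pair. The most common ratio of their values was taken as that of equal read numbers, which is an assumption, with a tolerance of 0.004 on the natural log scale. This gave 1.56 for replicate 1 over 2 from 252 of 1046 genes, 1.17 for replicate 1 over 3 from 255 of 1170 and 1.33 for replicate 3 over 2 from 253 of 952. Absolute depth stays unknown, so no counting interval is given for expression values. Low values in replicate 2 rest on the fewest reads.

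A gene was called expressed at 1 FPKM or more in every replicate. For 27 gene lists, the share of expressed members was compared with that of all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. These lists hold 504 distinct genes in the table, and 1 listed symbol was not found in it. Genes are not independent replicates, so these p-values describe the libraries. In each Hox cluster, Spearman's rho between paralogue number and mean log2(FPKM + 1) was tested by an exact permutation test of the pairings for 9 genes and with 100000 resamples for 10 or 11 genes, adjusted over 4 clusters. The spread between replicates was the SD of log2(FPKM + 1) for genes with a mean of at least 10 FPKM. The pseudocount of 1 understates differences of low genes. The gene lists, the thresholds, these tests, most alternatives and the rule for named genes were fixed before the data were examined.

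Named genes were chosen by this rule: members of the lists, the 20 genes with the highest mean, the 10 most variable genes with a mean of at least 10 FPKM, the 10 regions with the highest score, the 10 longest regions, and the 10 highest genes of the Sox, Pou, Pax, Fox, Gata, Tbx, Zic, Irx, Lhx and Nkx families outside the lists. Genes named outside this rule are said to have been chosen after their values were seen, and the highest genes are named without small RNA genes. Symbols were looked up in a table of Ensembl names, which held 22804 of the 24002, and in a RefSeq table of another mouse assembly, which held 22602. The latter was used for no coordinate. The values of some list members are not reported here.

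Added after the data were seen were the removal of small RNA genes by symbol, 5 more gene lists, ratios of gene pairs, the deviation of each list in each replicate and the densities of regions by score. For the deviation, each gene with a mean of at least 1 FPKM was set against its own mean over the replicates in log2(FPKM + 1), and the list median was ranked among 10000 random lists of the same size, drawn within 20 bins of mean expression. Alternatives were thresholds of 0.5 and 5 FPKM, a pseudocount of 0.1, no filter on low values, another background, upper quartile scaling, each replicate left out in turn, other score minima and merging of regions. On simulated reads for 24002 genes, a depth ratio of 1.5 was recovered as 1.5. On the real expression calls, the list test called 100% of planted lists of 25 genes and 0% of random ones. Planted lists were drawn mostly from expressed genes, so their call was to be foreseen. With 12397 genes of the real data, a list of 20 genes lowered in replicate 1 was placed at percentile 0, and 2% of 100 random lists fell outside the central 95%. The planted step was larger than the list deviations found, so this check does not show how small a shift is detected. A planted fall over 39 Hox genes gave rho of -1. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

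Relations between regions and genes at promoters or farther away were planned and not run, because gene positions in mm9 were not used here. Expression and accessibility are therefore described side by side and were not joined.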

Results

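R1 is a mouse embryonic stem cell line. R1 cells were grown with 15% serum replacement and 1000 U/ml LIF, a cytokine that maintains self-renewal. They were formed into embryoid bodies in hanging drops over 48 h and then exposed to retinoic acid, a morphogen that patterns the embryonic hindbrain and spinal cord, at 0.5 mM as the labels give it, with sampling at day 6. Micromolar doses are usual in such protocols, so the unit of this dose is uncertain. Polyadenylated RNA was sequenced in 3 samples, and accessible chromatin was profiled in 3 further samples by ATAC-seq, in which Tn5 transposase inserts adapters into open DNA. All 6 samples share this condition, so the data give levels at day 6 and no change from an untreated or earlier state. The series concerns how expression and accessibility measured in matched cells relate to each other. The RNA-seq table gave FPKM for 24002 genes in each replicate, and the accessible regions of the 3 ATAC-seq samples came as a joint set of 495233. FPKM summed to 494246 in replicate 1, 477760 in replicate 2 and 524717 in replicate 3. Read totals are unknown, but the steps between low values put the depth of replicate 1 at 1.56 times that of replicate 2 and 1.17 times that of replicate 3. The labels do not say that replicates came from separate cultures, so the spread between them may be technical.

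Among the highest FPKM outside the small RNA genes were those of tubulin and translation genes. Tuba1a, a neuronal alpha-tubulin, reached 2807 ± 107 FPKM (SD, n = 3), Stmn1, a regulator of microtubules, 1587 ± 33.3 and Tubb2b, a neuronal beta-tubulin, 1452 ± 56.3. The translation factor gene Eef1a1 stood at 2561 ± 11.2, Ptma at 1502 ± 10.3 and the ribosomal protein gene Rplp1 at 1349 ± 31.5. Of the 24002 genes, 12171 (50.7%) had at least 1 FPKM in every replicate and are called expressed here, 525 had a mean of at least 100 FPKM, and 5567 were listed at 0 in every replicate. Replicate pairs correlated across 12671 genes with Pearson r of log2(FPKM + 1) between 0.967 and 0.974 and Spearman's rho between 0.985 and 0.989. Without small RNA genes, named by their symbols after the data were seen, r lay between 0.995 and 0.996. These coefficients are across genes, which are not independent replicates, and carry no p-value.

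Most genes of retinoic acid signalling were expressed, some of them at high levels, with a list median of 14.5 FPKM. Cyp26a1 and Cyp26b1, which encode enzymes that degrade retinoic acid, stood at 155 ± 18.8 and 153 ± 4.09 FPKM (SD, n = 3). The binding protein genes Crabp1 and Crabp2 stood at 121 ± 2.88 and 119 ± 2.37 FPKM, and Dhrs3, which encodes a retinal reductase, at 48.4 ± 3.13. Among the nuclear receptors, Rara (30.6 ± 0.647) and Rarb (30.1 ± 0.886) lay far above Rarg (3.70 ± 0.621). Of 26 retinoic acid signalling genes, 24 were expressed, a share of 92.3% against 50.7% of the other genes (Fisher's exact test, two-sided, adjusted p = 4.9e-05 over 27 lists). The remaining members were the retinaldehyde dehydrogenase genes Aldh1a1 (0.252 ± 0.0524) and Aldh1a3 (0.0182 ± 0.0121), whereas Aldh1a2 stood at 11 ± 0.238 FPKM.

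Hox genes, which set position along the body axis, were expressed at 1 FPKM or more in paralogue groups up to 9 and not in groups 10 to 13. Of 27 genes of paralogue groups 1 to 9, 25 were expressed, with a median of 30.1 FPKM, and of 12 genes of groups 10 to 13 none was, the highest being Hoxb13 at 0.765 ± 0.212 FPKM (SD, n = 3). The highest levels were those of Hoxb8 (268 ± 10.8), Hoxb9 (208 ± 7.60), Hoxa5 (150 ± 3.35) and Hoxc4 (101 ± 1.11). Below the threshold within groups 1 to 9 were Hoxb1 (0.194 ± 0.0414), a gene of hindbrain rhombomere 4, and Hoxd9 (0.923 ± 0.114). By cluster, 8 of 11 HoxA, 8 of 10 HoxB, 5 of 9 HoxC and 4 of 9 HoxD genes were expressed. The division between groups 9 and 10 was chosen after the values were seen. At a threshold of 0.5 FPKM Hoxb13 (0.913, 0.523 and 0.860 FPKM in the replicates) would count as expressed.

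**Figure D1:**
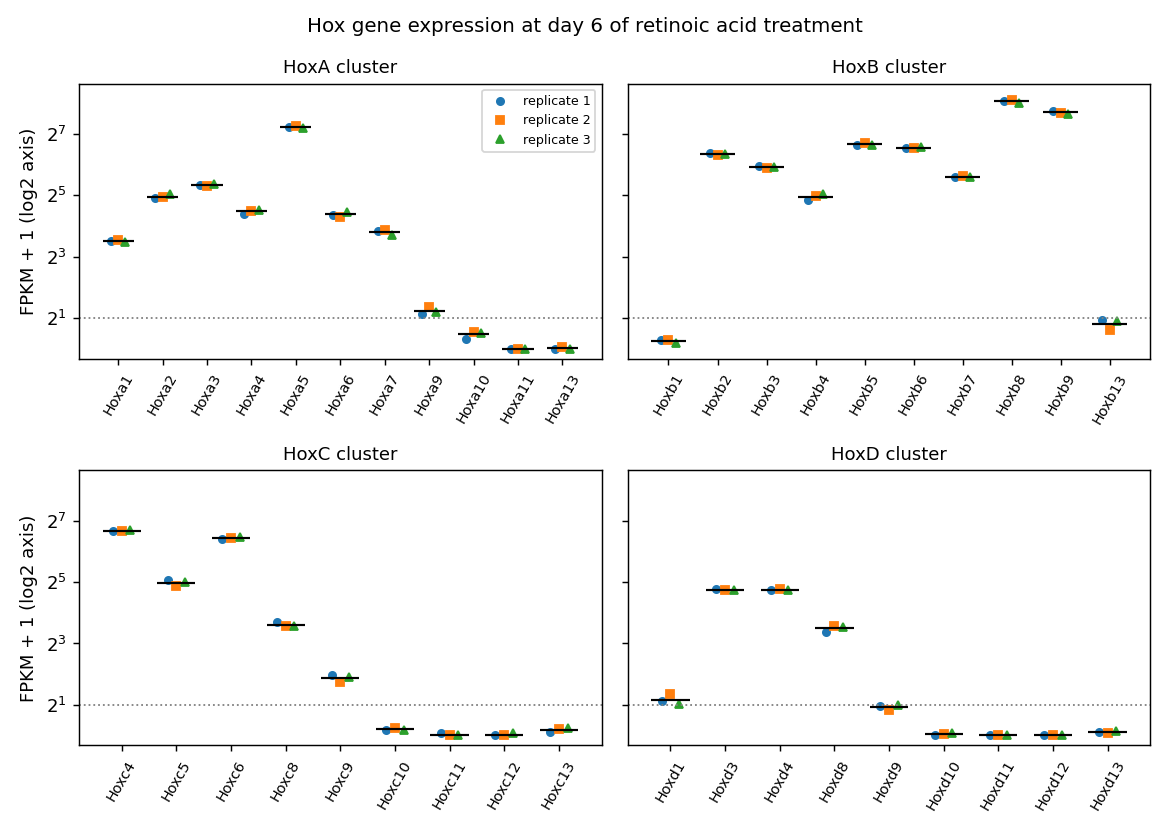
FPKM + 1 on a log2 axis for the 39 Hox genes of the HoxA, HoxB, HoxC and HoxD clusters, ordered by paralogue number, with points for the 3 RNA-seq replicates, a line for the mean and a dotted line at 1 FPKM. Hoxb8 and Hoxb9 reach 268 and 208 FPKM, and the genes of groups 10 to 13 lie below the dotted line.

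Within clusters, the level fell with paralogue number in HoxA, HoxC and HoxD, and no trend was called in HoxB. The difference between clusters was not tested. Spearman's rho was -0.736 over 11 HoxA genes (adjusted p = 0.023 over the 4 clusters, permutation test, two-sided), -0.917 over 9 HoxC genes (adjusted p = 0.0052, exact permutation test) and -0.783 over 9 HoxD genes (adjusted p = 0.023, exact permutation test). For 10 HoxB genes the coefficient was 0.345 (adjusted p = 0.33, permutation test). Raw p-values were 0.0122, 0.00131, 0.0172 and 0.332 for HoxA, HoxC, HoxD and HoxB. Without the genes listed at 0 in every replicate, Hoxa11 and Hoxd12, the HoxA and HoxD trends lost their call (rho = -0.661 and -0.762, adjusted p = 0.0573 for each in permutation tests), where adjusted p ranged from 0.0184 to 0.0573 over 5 alternatives.

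As a whole list, Hox genes were expressed at a share not called different from that of other genes (25 of 39, 64.1% against 50.7%, Fisher's exact test, adjusted p = 0.178). Of the Hox cofactor and Cdx genes, 10 of 14 were expressed (adjusted p = 0.243, Fisher's exact test). Pbx3 (117 ± 2.70 FPKM; SD, n = 3), Meis2 (95.4 ± 2.86) and Meis1 (65.1 ± 0.283), partners of Hox proteins on DNA, were high. The caudal genes Cdx2 (0.622 ± 0.134), Cdx4 and Cdx1 were below 1 FPKM, with Cdx1 listed at 0 in every replicate. At a threshold of 5 FPKM the Hox list stood above the other genes (adjusted p = 0.0248, Fisher's exact test), where its adjusted p ranged from 0.0248 to 1 over 7 alternatives.

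Genes of neural progenitors and of neurons were expressed together. Fabp7, a radial glial fatty acid binding protein gene, stood at 910 ± 8.47 FPKM (SD, n = 3), Vim at 262 ± 4.85, Sox11 at 178 ± 8.49 and Sox4 at 172 ± 5.97. Of the neuronal genes, Tubb3 reached 645 ± 8.48, the growth cone gene Gap43 607 ± 23.3, Stmn2 420 ± 15.8 and the neurofilament gene Nefl 416 ± 11.3 FPKM. Of 27 neural progenitor genes, 25 were expressed (92.6%, Fisher's exact test, adjusted p = 4.0e-05), with Dbx1 (0.599 ± 0.0429) and Zic1 (0.113 ± 0.0298) below the threshold. Of 34 neuronal genes, 32 were expressed (94.1%, adjusted p = 1.0e-06, Fisher's exact test), with Phox2a (0.195 ± 0.128) among those below it. In replicate 1 the neuronal genes stood slightly above their own means, with a median deviation of 0.04 (log2), at percentile 99.99 of 10000 random lists matched on expression. In replicate 3 they stood below, at -0.03 (percentile 0.1), as did the neural progenitor genes, at -0.04 (percentile 0.09).

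Transcription factors of the ventral spinal cord and of somatic motor neurons were present, while most of those of the dorsal neural tube were near or below 1 FPKM. Olig2 and Nkx6-1, which mark motor neuron progenitors, stood at 33.5 ± 1.18 and 37.5 ± 1.56 FPKM (SD, n = 3), and the motor neuron genes Lhx3, Mnx1 and Isl1 at 47.6 ± 1.68, 44.7 ± 1.53 and 17.6 ± 0.452. Nkx2-2, a marker of the more ventral V3 domain, stood at 1.61 ± 0.169. Of the dorsal genes, Lbx1 (2.10 ± 0.251) was expressed, Olig3 and Msx1 had means of 1.11 ± 0.134 and 1.10 ± 0.186 without reaching 1 FPKM in every replicate, Pax3 stood at 0.0317 ± 0.0253, and Pax7 was listed at 0.00808, 0.0252 and 0 in the replicates. Of 16 dorsal neural tube genes, 1 was expressed (6.25%, Fisher's exact test, adjusted p = 0.00063), and of 11 ventral ones, 7 were (adjusted p = 0.628, Fisher's exact test). The shares of the dorsal and ventral lists were not tested against each other. At a threshold of 0.5 FPKM the dorsal call was lost (adjusted p = 0.0507, Fisher's exact test; range over 7 alternatives 2.5e-05 to 0.0507).

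Fore- and midbrain genes were mostly below 1 FPKM and hindbrain genes mixed. Otx2 (0.114 ± 0.0525 FPKM; SD, n = 3), a gene of the fore- and midbrain, lay near 0. The exceptions were Pax2 (17.9 ± 1.6), En1 (5.20 ± 0.511), Pax8 (5.12 ± 0.249), En2 (1.49 ± 0.116) and Pax5 (1.11 ± 0.0779), and Pax2, Pax8 and En1 are also known from spinal interneurons. Of 21 fore- and midbrain genes, 5 were expressed (23.8%, Fisher's exact test, adjusted p = 0.030). Of 11 hindbrain genes, 7 were (adjusted p = 0.628, Fisher's exact test), with Gbx2 at 21.3 ± 1.30 but Egr2, a rhombomere gene, at 0.0979 ± 0.0547. At a threshold of 0.5 FPKM the fore- and midbrain call was lost (adjusted p = 0.0540, Fisher's exact test; range over 7 alternatives 0.00050 to 0.0540).

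Genes of cholinergic, inhibitory and glutamatergic neurons and some glial and neural crest genes were present. Slc18a3, the vesicular acetylcholine transporter gene, stood at 61.5 ± 1.54 FPKM (SD, n = 3) and the further cholinergic genes Chat and Slc5a7 at 8.62 ± 0.329 and 4.59 ± 0.368. Slc32a1 and Gad1 of inhibitory neurons stood at 12.0 ± 0.190 and 6.81 ± 0.178. The glutamatergic gene Slc17a6 stood at 2.79 ± 0.0924, while Slc17a7, another such gene, was below the threshold at 0.572 ± 0.0788. Among glial genes, Slc1a3 stood at 31.3 ± 0.419 and Mbp at 20.5 ± 1.34, while the astrocyte gene Aqp4 stood at 0.0496 ± 0.0154. Sox10 (21.1 ± 1.21) and Foxd3 (13 ± 0.391), known from neural crest, were expressed, but Tfap2a (0.126 ± 0.0267) and Snai2 (0.112 ± 0.0587) were not. Fisher's exact test called none of these lists, with 8 of 13 neurotransmitter genes (adjusted p = 0.628), 8 of 14 glial genes (adjusted p = 0.821) and 9 of 18 neural crest genes (adjusted p = 1) expressed. Of the neural crest members, 6 are on another list. Outside the lists, the highest transcription factor genes of the families examined were Sox12 (59.9 ± 0.765), Pou3f3 (49.8 ± 1.78), Sox21 (41.7 ± 1.38), Foxk2 (27.0 ± 1.6) and Irx1 (26.3 ± 1.52).

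**Figure D2:**
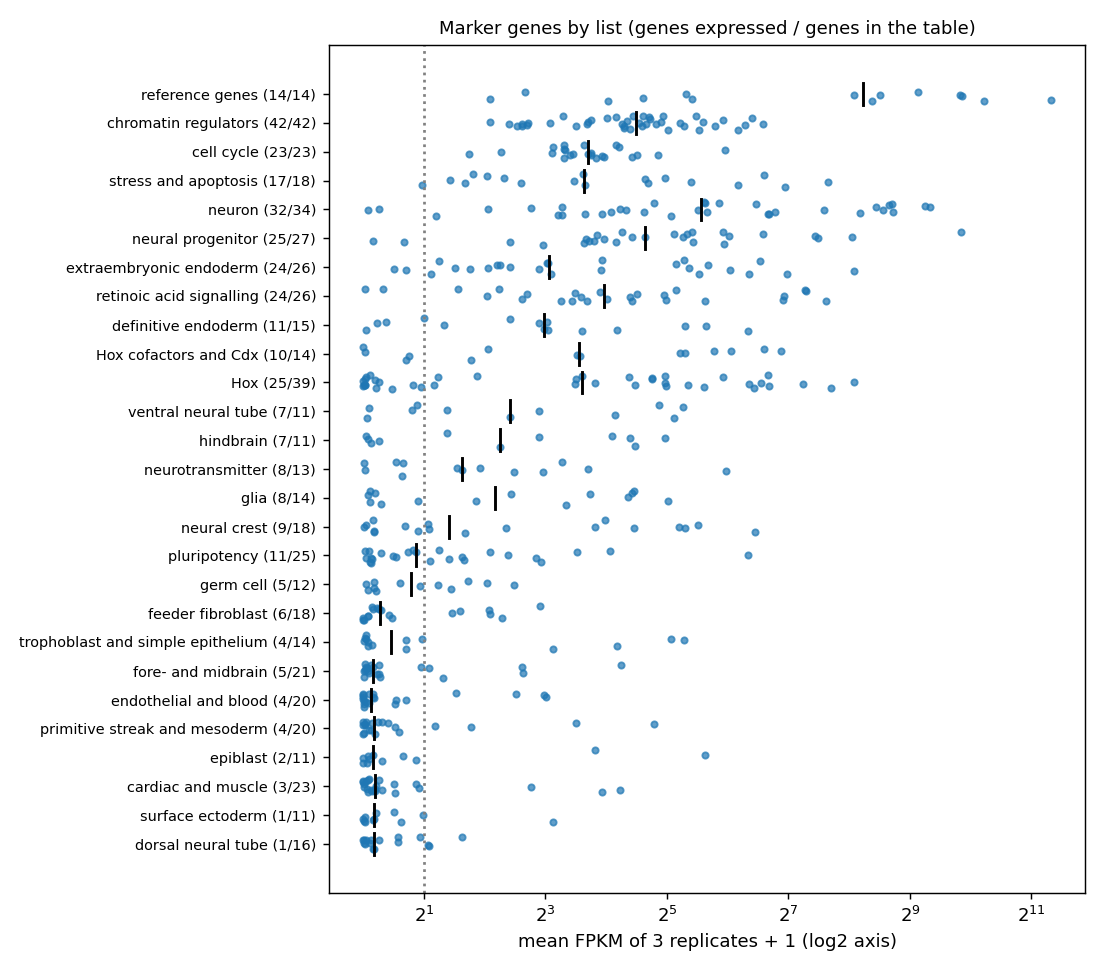
Mean FPKM + 1 of the 3 RNA-seq replicates on a log2 axis for each gene (points) of the 27 lists, with a black bar at the list median, a dotted line at 1 FPKM and the number of expressed genes beside each list's name. All 42 chromatin regulators lie above the dotted line, and 1 of 16 dorsal neural tube genes is expressed.

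The pluripotency genes Nanog and Pou5f1 were below 1 FPKM, while Sox2 and other members of the list were expressed. Nanog stood at 0.0879 ± 0.0318 and Pou5f1 at 0.815 ± 0.0792 FPKM (SD, n = 3). Sox2, which neural progenitors also use, stood at 79.5 ± 4.57, and Dppa5a, Klf4, Klf5 and Esrrb at 15.6 ± 2.48, 10.4 ± 2.35, 6.60 ± 1.72 and 6.17 ± 0.222. Of 25 pluripotency genes, 11 were expressed (44.0%, Fisher's exact test, adjusted p = 0.628), and of 11 epiblast genes, 2 were, Pou3f1 (48.4 ± 1.24) and Foxd3 (18.2%, adjusted p = 0.065, Fisher's exact test). Foxd3 is also on the neural crest list and Pou3f1 on the later list of motor neuron effectors. The epiblast members Lefty1 and Nodal stood at 0.243 ± 0.0245 and 0.0497 ± 0.00729. Of 12 germ cell genes, 5 were expressed (adjusted p = 0.628, Fisher's exact test), led by Mael at 4.56 ± 0.400. The pluripotency members with a mean of at least 1 FPKM had a median deviation of -0.11 (log2) in replicate 1, at percentile 0.08 of random lists. Against a background of genes above 0 in a replicate, the pluripotency (adjusted p = 0.0481; range over 7 alternatives 0.0481 to 0.843) and epiblast lists (0.0168; 0.0168 to 0.447) fell below the other genes in Fisher's exact test. At a threshold of 5 FPKM the germ cell list did so (adjusted p = 0.0162, Fisher's exact test; 0.0162 to 0.782).

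Genes of mesoderm, heart and muscle, blood vessels and surface ectoderm were mostly below 1 FPKM. T and Msgn1, genes of the primitive streak and paraxial mesoderm, were listed at 0 in every replicate, and Eomes stood at 0.0910 ± 0.0384 FPKM (SD, n = 3). The cardiac genes Tnnt2 and Myh6 stood at 0.0732 ± 0.0148 and 0.0927 ± 0.0351, and the endothelial genes Pecam1 and Kdr at 0.0700 ± 0.0423 and 0.438 ± 0.0359. Expressed were 3 of 23 cardiac and muscle genes (adjusted p = 0.00063), 4 of 20 primitive streak and mesoderm genes (adjusted p = 0.0135), 4 of 20 endothelial and blood genes (adjusted p = 0.0135) and 1 of 11 surface ectoderm genes (adjusted p = 0.0135), in Fisher's exact test. Several of these genes also serve neurons, such as Isl1 of the cardiac list and Lhx1 (26.7 ± 1.89) of the mesoderm list. So do Tal1 (7.07 ± 0.213), Gata2 (6.90 ± 0.226) and Gata3 (7.76 ± 0.0816), which mark V2b interneurons. The other expressed members were Gata4 (14.3), Pdgfra (10.3), Myl3 (5.80), Flt1 (4.71), Evx1 (2.44), Runx1 (1.88) and Tcf15 (1.26). Of these, Gata4, Pdgfra, Myl3, Flt1 and Runx1 were lower in replicate 1 than in both others, and Evx1 and Tcf15 were not. The surface ectoderm call was lost at thresholds of 0.5 and 5 FPKM (adjusted p = 0.0558 and 0.166) and without replicate 3 (adjusted p = 0.0637), with a range of 0.00142 to 0.166 over 7 alternatives of Fisher's exact test.

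Trophoblast and feeder fibroblast genes were expressed in part, at shares not called different from that of other genes. Krt18 and Krt8 stood at 38.1 ± 8.58 and 32.3 ± 8.92 FPKM (SD, n = 3), Gata3 at 7.76 ± 0.0816, Timp1 at 6.53 ± 1.6 and Col6a1 at 3.84 ± 0.849, while the trophoblast genes Elf5 (0.0576 ± 0.0422) and Tfap2c (0.0527 ± 0.0130) and the fibroblast collagen genes Col1a1 (0.167 ± 0.0345) and Col3a1 (0.103 ± 0.0227) were near 0. Of 14 trophoblast and simple epithelium genes, 4 were expressed (28.6%, adjusted p = 0.178), and of 18 feeder fibroblast genes, 6 were (33.3%, adjusted p = 0.230), in Fisher's exact test. With a background of genes above 0 in a replicate, both lists stood below the other genes (adjusted p = 0.0149 and 0.0481, Fisher's exact test), and feeder fibroblast genes also did at a threshold of 5 FPKM (0.00263). Over 7 alternatives adjusted p ranged from 0.0149 to 0.873 for the trophoblast list and from 0.00263 to 0.228 for the fibroblast list.

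Beside the neural genes, genes of extraembryonic endoderm, the lineage of yolk sac epithelium, were expressed. The basement membrane genes Sparc, Col4a1 and Lamb1 stood at 269 ± 35.6, 125 ± 26.6 and 50.4 ± 10.8 FPKM (SD, n = 3), and the endoderm factors Gata4, Sox17 and Gata6 at 14.3 ± 3.30, 7.22 ± 1.52 and 7.09 ± 1.5. Other members were low, among them Ttr (4.35 ± 0.777), Afp (3.17 ± 0.435) and Hnf4a (1.84 ± 0.269). Of 26 extraembryonic endoderm genes, 24 were expressed (92.3%, Fisher's exact test, adjusted p = 4.9e-05), with Thbd (0.637 ± 0.155) and Apob (0.420 ± 0.0718) below the threshold. At a threshold of 5 FPKM the call was barely kept (adjusted p = 0.0430, Fisher's exact test, range over 7 alternatives 5.0e-05 to 0.0430). Of 15 definitive endoderm genes, 11 were (73.3%, adjusted p = 0.178, Fisher's exact test), with Cxcr4 at 48.7 ± 0.333 and Cldn6 at 38.2 ± 8.11. In each of these lists 6 members are on another list.

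These endoderm genes were lower in replicate 1. Sparc stood at 228, 287 and 293 FPKM in replicates 1, 2 and 3, Col4a1 at 94.2, 140 and 141, and Gata4 at 10.5, 15.6 and 16.7. Of the 24 extraembryonic endoderm genes with a mean of at least 1 FPKM, 22 were lower in replicate 1 than in both others. Their median deviation from their own means was -0.27, 0.15 and 0.13 (log2) in the 3 replicates, at percentiles 0, 100 and 100 of 10000 random lists matched on expression. For 11 definitive endoderm genes the deviations were -0.32, 0.14 and 0.19, with 8 lower in replicate 1 than in both others. Over 12432 genes the median deviation in replicate 1 was 0.00016. The percentiles describe these libraries and test no difference between conditions.

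**Figure D3:**
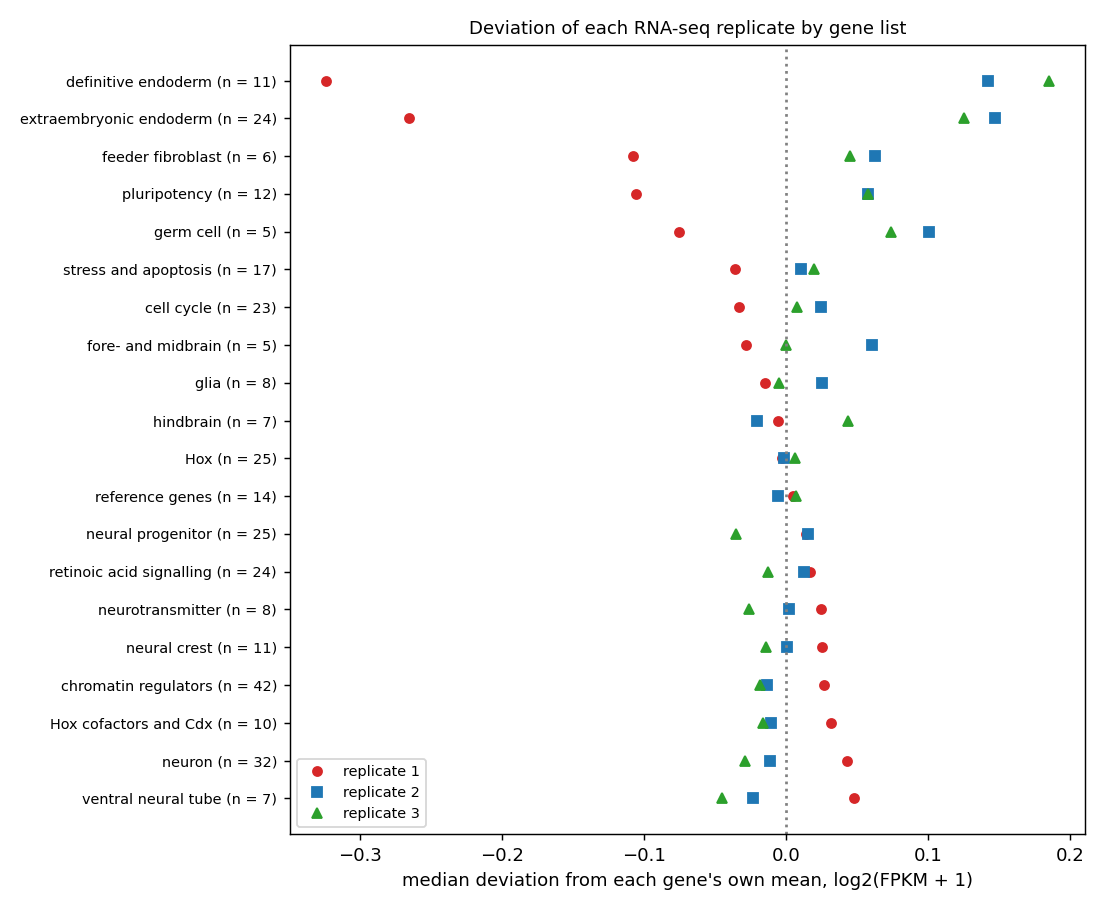
Median deviation of each list's genes from their own mean over the replicates, in log2(FPKM + 1), for the 20 lists with at least 5 genes of mean 1 FPKM or more, with a symbol for each of the 3 RNA-seq replicates and n giving the genes in each list. Definitive and extraembryonic endoderm genes lie at -0.32 and -0.27 in replicate 1 and above 0 in replicates 2 and 3.

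Genes of chromatin regulation, the cell cycle, stress responses and general cell maintenance were broadly expressed. Hdac2 stood at 94.8 ± 1.92 FPKM (SD, n = 3), the nucleosome remodelling genes Chd4 and Smarca4 at 83.5 ± 1.48 and 70.9 ± 2.75, Pcna at 61.4 ± 1.49 and the proliferation gene Mki67 at 12.4 ± 0.363. The p53 targets Cdkn1a and Bax stood at 40.9 ± 0.956 and 122 ± 5.52, and Hspa5, of the unfolded protein response, at 200.2 ± 3.75. Expressed were 42 of 42 chromatin regulators (adjusted p = 1.4e-11), 23 of 23 cell cycle genes (adjusted p = 2.2e-06), 14 of 14 reference genes (adjusted p = 0.00048) and 17 of 18 stress and apoptosis genes (94.4%, adjusted p = 0.00050), the exception being Pmaip1 (0.946 ± 0.138), in Fisher's exact test. The stress call was lost at a threshold of 5 FPKM (adjusted p = 0.0763, Fisher's exact test; range over 7 alternatives 0.00016 to 0.0763). Lists of widely used genes, above all the reference genes, were bound to exceed the other genes, so their calls say nothing about this condition.

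The genes that varied most between replicates were small RNA genes. Mir6990 was listed at 56675 FPKM in replicate 1 and at 0 in both others, and Snora68 at 12998 in replicate 2 and at 0 in both others. Small RNA genes made up 35.3%, 32.8% and 38.8% of summed FPKM in replicates 1, 2 and 3. Among 6116 genes with a mean of at least 10 FPKM the median SD of log2(FPKM + 1) was 0.05, and 27 genes had an SD above 1, all of them small RNA genes. Of the 20 most variable other genes, 16 were lower in replicate 1 than in both others, among them Tinagl1 (20.2, 37.5 and 37.3 FPKM), Plac8 (12.5, 22.0 and 22.4), Clu (59.2, 102 and 100.4) and Krt8 (22.0, 37.3 and 37.6), named after their values were seen. Eif3j1 and Eif3j2 are near-identical copies that may share reads, which was not tested, so each is uncertain singly. They stood at 9.38, 0.0694 and 0.0508 FPKM and at 18.1, 28.6 and 28.4, whereas their sum was 27.5, 28.7 and 28.4. Both were chosen after their values were seen.

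Accessible regions were numerous, short and mostly of low score. The 495233 regions covered 240.2 Mb, had a median width of 332 bp (quartiles 264 and 608 bp, range 10 to 13702 bp) and did not overlap. The score, the authors' own value per region on an unstated scale, ran from 3.62 to 3886 with a median of 5.24. At a score of at least 10 there were 89421 regions (18.1%), at least 50 there were 15612 (3.15%) and at least 100 there were 8216 (1.66%). Width and score rose together across regions (Spearman's rho = 0.728), with a median width of 791, 1511 and 1674 bp above these scores. The region with the highest score lay on chromosome 2 at 98506250 to 98507634 (mm9, score 3886), followed by chromosome 1 at 24619247 to 24620179 (score 2868) and chromosome 12 at 3109724 to 3110270 (score 2213). Of the 10 highest, 4 lay on chromosome 2 between 98502258 and 98507634. The longest region lay on chromosome 5 at 143572825 to 143586526 (13702 bp, score 199). The gene and repeat content of these regions was not analysed here, so their high scores or lengths are not read as open chromatin. The joint set has no replicates.

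Over all scores the sex chromosomes held few regions per Mb. Autosomes carried 173 (chromosome 14) to 239 (chromosome 11) regions per Mb up to the last region on each, against 18.8 on X and 17.9 on Y. The last region ended at 2.90 Mb on Y, against 61.3 Mb on chromosome 19 and 167 Mb on X. Densities on Y therefore cover a short stretch. The X chromosome held 3131 regions and the Y chromosome 52. Regions on X had a median score of 9.81 and those on Y of 19, against 5.18 to 5.36 on the autosomes. The density on X relative to that on all autosomes was 0.0944, and at scores of at least 10, 50 and 100, chosen after the data were seen, it was 0.262, 0.415 and 0.386. The Y chromosome carried 13.1, 4.82 and 2.07 regions per Mb at these scores, against 31.1 to 43.0, 4.80 to 9.06 and 2.36 to 4.79 on the autosomes, below their range at 10 and 100 and at its lower end at 50, on few regions. In the RNA, the Y-linked genes Eif2s3y and Ddx3y stood at 16.0 ± 0.322 and 6.83 ± 0.368 FPKM (SD, n = 3), and Xist, the RNA of X inactivation, at 0.261 ± 0.0255, all 3 named after their values were seen.

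**Figure D4:**
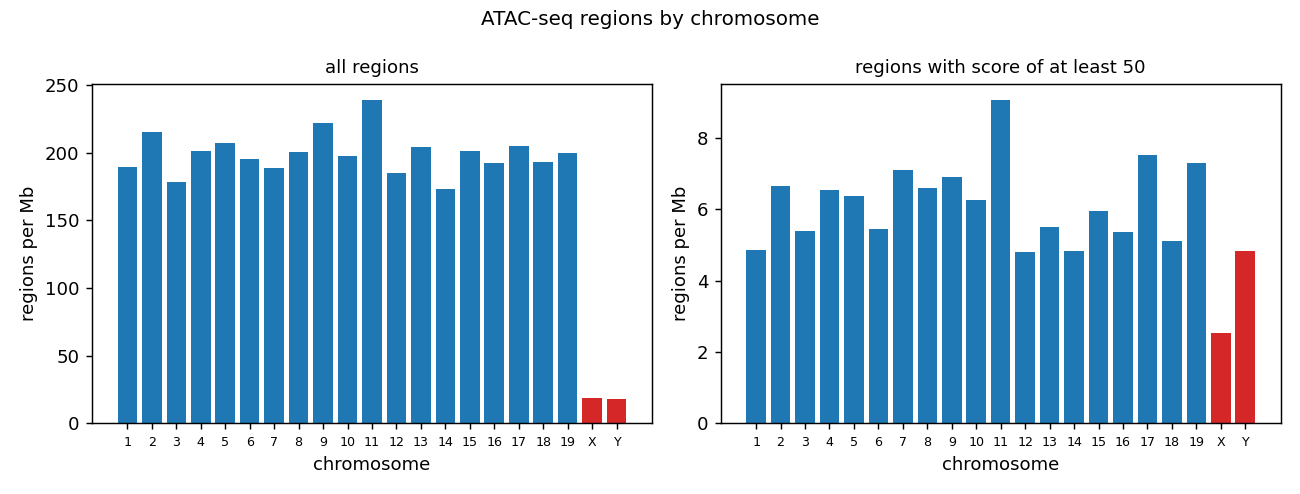
Regions per Mb (bars) on chromosomes 1 to 19, X and Y for all regions and for those with a score of at least 50, in mm9, with the last region on each chromosome as its length. That length was 2.90 Mb on Y. All regions give 173 to 239 per Mb on autosomes, 18.8 on X and 17.9 on Y, and scores of at least 50 give 4.80 to 9.06, 2.55 and 4.82.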

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

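Settings without small RNA genes, the deviations in replicate 1, the count of Hox paralogues 1 to 9 and the score minima were tested only after the result was seen; the other alternatives were planned. No call turned its direction, but 6 lists without a call changed sign in 10 of 189 cases (neural crest, pluripotency, neurotransmitter, glia, hindbrain and ventral neural tube), none of them called there. The mean Pearson r between replicates was 0.958 with a pseudocount of 0.1, 0.990 without a filter on low values, 0.995 without small RNA genes, and 0.966 to 0.974 with a replicate left out; Spearman's rho was 0.983 without the filter, 0.995 without small RNA genes and 0.985 to 0.988 with a replicate left out. The cause was not tested, except that small RNA genes lowered both. Expressed genes numbered 8570 at 5 FPKM and 13068 at 0.5 FPKM. Of the 6 gene lists below the other genes, 3 passed at 0.5 FPKM, and 10 lists passed against a background of genes above 0 in a replicate, which raises the share of the other genes. Calls of single lists were kept in 176 of 189 cases, gained in 7 and lost in 6. With genes listed at 0 left out, rho for HoxA was -0.661 and for HoxD -0.762, each with 1 gene fewer. The regions with the highest scores, 50% of all, numbered 247616 by construction. Genes with an SD above 1 numbered 0 without small RNA genes, since all 27 were such genes. The density of regions on X relative to autosomes was 0.262, 0.415 and 0.386 at scores of at least 10, 50 and 100. Relative to the main setting, the deviation of extraembryonic endoderm genes in replicate 1 stayed between -0.32 and -0.24. No paired analysis was possible because the region set does not separate replicates and no groups were tested against each other. Not run were the alternatives for promoter accessibility and expression, promoter accessibility of the gene lists and distal regions near the gene lists. Depth is known only relatively, which limits genes near 0 FPKM.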

Other observations

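All tests in this part were chosen only after the results were seen. Genes of axon growth and of motor neuron function were broadly expressed. Of 29 axon guidance genes, 28 were expressed (adjusted p = 5.9e-07 over 5 added lists, Fisher's exact test), among them Nrp2 (48.8 ± 3.46 FPKM; SD, n = 3), Robo1 (31.4 ± 1.55) and Ntn1 (31.2 ± 1.85), while Dcc, a netrin receptor gene, stood at 16.3 ± 0.831. Of 16 motor neuron effectors, 15 were expressed (adjusted p = 0.0013, Fisher's exact test), with the intermediate filament gene Prph at 108 ± 1.14, Ache at 22.9 ± 0.914 and Isl2 at 15.3 ± 0.721. Of 18 genes of spinal interneuron classes, 14 were expressed (adjusted p = 0.031, Fisher's exact test), with Bhlhe22 at 20.7 ± 0.998 and the V3 gene Sim1 at 0.0707 ± 0.0167. Of 20 glutamate, GABA and glycine receptor genes, 16 were expressed (adjusted p = 0.015, Fisher's exact test), led by Grik5 (34.8 ± 0.538). Of 25 imprinted genes, 21 were expressed (adjusted p = 0.0016, Fisher's exact test), with Nnat at 924 ± 10.8, Meg3 at 346 ± 42.6 and H19 at 182 ± 13. These lists were written with the values known, so their p-values are no independent evidence.

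Within libraries, 3 subunits of the BAF chromatin remodelling complex known from neurons exceeded a progenitor counterpart, and others did not. The log2 ratio was 0.81 ± 0.02 (SD, n = 3) for Dpf1 over Phf10, 0.45 ± 0.13 for Actl6b over Actl6a and 0.38 ± 0.05 for Ss18l1 over Ss18. By contrast, Dpf3 (5.12 ± 0.884 FPKM) lay below Phf10 (16.8 ± 0.530), and Smarcd3 (5.53 ± 0.846) below Smarcd1 (59.6 ± 1.48). Hdac2 exceeded Hdac1 by 2.09 ± 0.02 and Rara exceeded Rarg by 3.06 ± 0.22, whereas Cyp26a1 over Cyp26b1 gave 0.01 ± 0.22, within the spread. Each ratio except the last had the same sign in 3 of 3 replicates, and 3 replicates cannot give an exact two-sided sign-flip p under 0.25. FPKM of different genes also depends on gene models and mappability, so the ratios describe deposited values.

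Extraembryonic endoderm genes were lower in replicate 1 than in the other RNA-seq libraries, with 88.9% of the members on no other list, 16 of 18, below both others. The list's percentile of 0 among random lists of genes at the same expression (test of library depth) restates the pattern. Those random lists averaged -0.00087 in replicate 1, which argues against a depth effect shared by genes at that expression. Gene length was not matched. Against scaling of replicate 1 stands the median deviation of 0.00016 over 12432 genes. Upper quartile scaling changed little, from -0.27 to -0.26, and so tested little. A smaller share of extraembryonic endoderm cells in replicate 1 may be involved but stays open, because the 88.9% restates the pattern and decides nothing. Other lists also moved in replicate 1, with definitive endoderm genes at -0.32 (percentile 0), pluripotency genes at -0.11 (0.08), feeder fibroblast genes at -0.11 (2.36), cell cycle genes at -0.03 (1.93), neuronal genes at 0.04 (99.99) and chromatin regulators at 0.03 (98.7), while Cxcr4 of the definitive endoderm list stood at 48.7, 49.1 and 48.4 FPKM. Some listed genes, such as Sparc and Apoe, are active in other cells as well, and no biological explanation was tested.

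Over all scores the X and Y chromosomes held few regions, and those present had higher scores. At scores of at least 10, 50 and 100 Y carried 13.1, 4.82 and 2.07 per Mb against autosomal lows of 31.1, 4.80 and 2.36. Densities on Y were counted over the 2.90 Mb up to its last region. If every X region had its score halved by a single copy of the chromosome, the density of X regions relative to autosomal regions at 2 times the score would be steady, but it ran from 0.547 to 1.05 over scores of 10 to 100, a 1.92-fold spread. A score minimum that leaves out low regions where coverage is lower stays open: relative density on X was 0.262 at scores of at least 10 (95% interval for counting error 0.249 to 0.275) against 0.0944 at the minimum of 3.62, which follows from the higher scores on X and decides nothing. Relative density on X was 0.386 at scores of at least 100 and 0.162 at 200. A score that is not linear in coverage, filtering by the authors and the gene content of X were not tested, and no biological explanation was tested.

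Small RNA genes had very high FPKM that came and went between replicates. Of the genes with a mean of at least 3 FPKM and a 0 in a replicate, 100% were small RNA genes, 27 of 27, whereas 0 of 10254 other genes at that level had such a 0. A handful of fragments divided by a very short gene length may give such values, but the 100% restates the pattern. Identical values recurred between genes, as in Mir218-2 and Mir219a-1, each at 1234 FPKM in replicate 2 and at 0 in both others. Mir692-2 and Mir692-3 shared 22428 and 19937 FPKM in replicates 2 and 3. Equal values do not tell few fragments from reads shared between near-identical genes, so they decide nothing. Fragment numbers and gene lengths were not used here, so the cause stays open. Of the 34 small RNA genes at that level, the remaining ones had no 0, such as Mir692-2 at 22532, 22428 and 19937 FPKM. No biological explanation was tested.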
